A study of Mus musculus with 12 samples.

How the data were processed

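RNA-seq was carried out on mouse splenic CD4+ T cells in 12 libraries, 3 groups from the same 4 mice on a C57/Bl6 background. Per the labels, naive CD62L+ cells were purified magnetically, with negative enrichment of CD4+ cells followed by CD62L beads, and were taken at 0 h or after 5 h. Cells at 5 h had been kept on plates coated with anti-CD3 and anti-CD28, which stimulate the T cell receptor and its main co-receptor. The medium held interleukin 6, interleukin 1β, TGF-β and antibodies that neutralise interleukin 4, interleukin 12 and interferon γ, a mixture that favours T helper 17 (Th17) differentiation. In 1 of the 5 h groups the medium also held 10 µM harmine, a plant β-carboline that inhibits the kinase DYRK1A. The labels give different antibody and TGF-β concentrations for these conditions in different fields, so none is given here, and they name no vehicle for the cells kept without harmine.

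Per the labels' protocols, RNA was isolated on Qiagen RNeasy columns, reverse transcribed and amplified as full-length cDNA with the SMART-Seq v4 kit, and made into libraries with Nextera XT. This kit keeps no record of the transcribed strand and adds no molecular identifiers, so PCR copies of 1 molecule are counted separately. The authors deposited raw read counts per Ensembl gene, 1 table per library, whose values are whole numbers with no normalization. Per the submitters' processing notes, HTSeq, STAR, Picard and the genome build GRCm38 were used. Their roles, settings and annotation release, and whether counting used strand, are not given in the sources used here. Reads from overlapping genes, from a gene and an antisense partner, or from near-identical copies may therefore have been divided in ways the counts do not show.

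Each table listed 53465 gene identifiers, and no entry was a summary line. Of these, 53360 matched the GENCODE M21 annotation of GRCm38, which gave symbols, classes and coordinates, and 105 did not. Library totals ran from 3123800 to 4355566 counts. A count of 0 in 1 library leaves room for up to 3 counts, or 0.689 to 0.960 CPM, the unit of counts scaled by library size, depending on the library. Intervals and floors of this kind cover counting error only. The groups, the tests, the lists and the alternatives were fixed before the data were examined, except where the text says otherwise.

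Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 10950, and libraries were scaled with TMM factors. A quasi-likelihood model with group as its only term was fitted to all 12 libraries, which shared 1 estimate of the spread. The contrasts were Th17 conditions at 5 h against naive cells at 0 h, called stimulation here, and Th17 conditions with harmine against those without it. The test was edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. Log2 fold changes are given with standard errors obtained from the F statistic, and levels as CPM scaled by TMM, with the standard deviation (SD) over 4 mice. Where all 4 libraries of a group had 0 counts, the fold was computed against 3 counts over the group and is written as a lower bound. Where a group held 1 to 3 counts, the ratio carries an exact 95% counting interval. The common biological coefficient of variation was 0.221.

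Lists of genes came from textbook knowledge: 26 of pathways and programs and 9 of cell types that the sort could keep or leave in. Each was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of its kind within a contrast. The test compares the members with all other genes. It was repeated with an estimated correlation and with fry. Counts of members past the threshold are over all tested genes, and counts adjusted over the list alone stand beside them.

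The genes named in the text come from a rule fixed beforehand. It takes, in each contrast, the 6 largest rises and 6 largest falls among named genes past the threshold, with a mean of at least 10 CPM in the higher group and 1 direction in all 4 mice. Predicted genes and pseudogenes were passed over there. It adds up to 4 members per list with the largest change among those past the threshold, or the 2 most abundant members where none passed, and 10 fixed genes. The rule names 200 genes, and the text gives 117 of them, a subset chosen after their values were seen. Of these 117, 35 share exon sequence with another annotated gene. That share is over 10% of the exon length in 11, which are Clk3, Csf1r, Csf2, Dhcr24, Fosl1, Foxp3, Hspa1a, Ifng, Pim1, Srsf2 and Txnip, and their counts are uncertain. So are those of genes with near-identical copies, such as Hspa1a, Gbp9, the Srsf genes and the hemoglobin genes.

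The pipeline was tested on simulated counts drawn for the real genes with 200 genes changed, all with a mean of at least 10 CPM in Th17 conditions. In the simulated harmine contrast, over 10161 genes, it recovered 24% of genes changed by 1.5-fold, 70% at 2-fold, 100% at 4-fold and 100% at 8-fold, and 5.16% of its calls were unchanged genes. In the simulated stimulation contrast, over 10171 genes, it recovered 18%, 86%, 98% and 100% at the same sizes, and 8.49% of its calls were unchanged genes.

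The same mouse gave 1 library to each group, per the donor numbers in the labels, so the numbers pair the libraries. The deviations of the paired libraries from their group means correlated at 0.116, 0.169, 0.174 and 0.0700 across genes between the 5 h groups for mice 1 to 4. Between 0 h and Th17 conditions they correlated at 0.0390, −0.121, 0.0810 and 0.0180. A fit with mouse as a block was chosen beforehand as an alternative. The others were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom and no filter on low counts. A stricter filter of 5 CPM in 4 libraries, a fit of only the 8 libraries compared, and leaving out mitochondrial, ribosomal protein, hemoglobin and immunoglobulin genes were also chosen then, as were leaving out each library in turn and a bound of 2-fold. A fit without the 5 h libraries of mouse 2 was added after seeing the data. Figures were drawn with matplotlib 3.10.9.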

Results

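The data set holds gene counts from 12 RNA-seq libraries of mouse splenic CD4+ T cells, 4 libraries in each of 3 groups. The groups are naive cells at 0 h, cells after 5 h in Th17 conditions, and cells after 5 h in Th17 conditions with 10 µM harmine, an inhibitor of the kinase DYRK1A. Each of the 4 mice gave a library to each group. Library totals were 3671260 ± 473533 counts at 0 h, 3707710 ± 447228 in Th17 conditions and 3742440 ± 300073 with harmine (mean ± SD, n = 4). Between 14756 and 16747 genes had at least 1 count in a library, and 10950 genes entered the tests.

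The first principal component held 66.1% of the variance and separated 0 h from 5 h, and the second, with 9.99%, separated the 5 h groups. The 5 h libraries of mouse 2 stood apart from the other mice. In Th17 conditions, the chi-square per degree of freedom between mouse 2 and another mouse was 33.9 to 34.6, against 3.14 to 5.54 between the other mice. With harmine it was 9.09 to 9.54 against 3.81 to 4.82. Ribosomal protein genes took 4.44% of the counts in the Th17 library of mouse 2 and 2.70 to 2.92% in the others, and mitochondrial genes 1.26% against 0.788 to 0.853%.

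The stimulation contrast sets CD4+ T cells after 5 h of Th17 conditions against naive cells at 0 h. No group was kept for 5 h without stimulation, so its effect cannot be told apart from that of time in culture. Genes of the Th17 program rose. Il17f, encoding interleukin 17F, went from 0.418 ± 0.514 to 42.7 ± 27.2 CPM (mean ± SD, n = 4), a log2 fold change of 6.64 (SE 0.67). Rorc, encoding the Th17 transcription factor RORγt, went from 2.33 ± 1.29 to 48.3 ± 11.4 CPM, with a log2 fold change of 4.31 (SE 0.33). Il2, the T cell growth factor, and Il2ra, its receptor α chain, rose by 5.00 (SE 0.33) and 4.92 (SE 0.17) on the log2 scale, and Il2ra reached 1335 ± 129 CPM. Transcripts of quiescent cells fell. Txnip, encoding an inhibitor of glucose uptake, dropped from 1248 ± 23.0 to 39.8 ± 4.32 CPM, a log2 fold change of −4.97 (SE 0.13).

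By edgeR's quasi-likelihood test, 6568 of 10950 genes passed an adjusted p of 0.05, 3275 higher and 3293 lower at 5 h. Of these, 1895 were higher and 2272 lower by at least 2-fold. At an unadjusted p under 0.05 there were 6982 genes. TMM scaling takes most genes as unchanged, while 6568 of 10950 passed here. With upper-quartile factors, 2924 genes were higher and 3603 lower, so the split depends on the scaling. Levels in CPM are shares of a library's counts, and a change in total RNA per cell would not be seen. Rises and falls of genes and lists in both contrasts are therefore relative to the other genes.

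The 6 largest rises and 6 largest falls were taken among named genes with a mean of at least 10 CPM and 1 direction in all 4 mice. The chemokine gene Ccl1 had no counts at 0 h and 32.4 ± 21.5 CPM at 5 h, at least 165-fold higher. Sphk1, encoding sphingosine kinase, was at least 96.8-fold higher at 19 ± 8.62 CPM, and Ccl20, encoding the ligand of the Th17 chemokine receptor CCR6, at least 58.3-fold higher at 11.4 ± 10.2 CPM. Akr1c18, encoding a steroid dehydrogenase, had 3 counts at 0 h and was 625-fold higher (95% counting interval 214 to 3035, adjusted p = 4.11e-10). Timp1, encoding a metalloproteinase inhibitor, had 1 count at 0 h and was 561-fold higher (interval 100.2 to 22186, adjusted p = 1.42e-09). Sema7a, encoding a semaphorin, rose by 8.22 on the log2 scale (SE 0.40, adjusted p = 3.99e-11). The falls were those of Tet1, a DNA demethylation enzyme, at least 99.2-fold lower from 20.8 ± 7.77 CPM, Adgre4, an adhesion receptor of myeloid cells, at least 91.4-fold lower, the integrin gene Itga7, at least 58.5-fold lower, and the lipopolysaccharide-binding protein gene Lbp, at least 49.0-fold lower. The iron exporter gene Slc40a1 had 3 counts at 5 h and was 435-fold lower (interval 149 to 2114). The heat shock gene Hspa1a had 1 count and was 517-fold lower (interval 92.4 to 20449), and its naive level was 35.9 ± 29.9 CPM. Adgre4 and Slc40a1 were low in mouse 3 at 0 h, at 8.16 and 36.8 CPM against 18.9 to 26.4 and 82.0 to 145 CPM, as were the myeloid genes Adgre1 and Cd68, and myeloid markers took 0.0620% of the counts at 0 h and 0.0180% at 5 h.

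Of the 16 measured Th17 program genes, 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 2.33 that stays the same with Ccl20 at its bound. The list passed at adjusted p = 4.56e-05, and at adjusted p = 0.0108 with an estimated correlation. Il21, encoding interleukin 21, rose by 7.71 on the log2 scale (SE 0.39) to 172 ± 20.1 CPM. Il17a, the gene of the signature Th17 cytokine, had 1 count at 0 h and 7.46 ± 5.39 CPM at 5 h, 108-fold higher (95% counting interval 19 to 4318, adjusted p = 0.000132).

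Growth and activation genes rose together. Ribosome biogenesis genes rose in 23 of 24 cases and fell in 0 (24 and 0 adjusted over the list alone), with a median log2 fold change of 1.83 (adjusted p = 3.12e-13, and 0.000596 with an estimated correlation). Among them, the small nucleolar ribonucleoprotein genes Nhp2, Gar1 and Dkc1 rose by 3.12 (SE 0.20), 2.30 (SE 0.19) and 2.24 (SE 0.12). Of the T cell activation surface genes, 15 of 16 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.61 (adjusted p = 3.28e-07, and 0.0237 with an estimated correlation). The inhibitory receptor gene Pdcd1 rose by 4.86 (SE 0.23), and the costimulatory receptor genes Tnfrsf9 and Tnfrsf4 by 4.16 (SE 0.16) and 3.54 (SE 0.17). IL-2 and STAT5 targets held 8 higher and 1 lower of 12 (8 and 1 adjusted over the list alone), with a median of 1.82 (adjusted p = 0.000745, and 0.0377 with an estimated correlation). NFAT targets held 10 higher and 2 lower of 15 (11 and 2 adjusted over the list alone), with a median of 1.21 (adjusted p = 0.00105, and 0.0237 with an estimated correlation). Irf8, a transcription factor gene, reached 1863 ± 157 CPM, and Csf2, encoding the cytokine GM-CSF, had 1 count at 0 h and was 60.03-fold higher (interval 10.3 to 2413).

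Metabolic lists rose too. Of the cholesterol synthesis genes, 16 of 20 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 1.69 (adjusted p = 3.11e-06, and 0.0108 with an estimated correlation). The sterol demethylase gene Cyp51 rose by 3.60 (SE 0.14) to 656 ± 21.9 CPM, the isoprenoid enzyme gene Idi1 by 3.28 (SE 0.32) and the squalene epoxidase gene Sqle by 2.72 (SE 0.15). The ATF4 and amino acid response held 17 higher and 2 lower of 21 (17 and 2 adjusted over the list alone), with a median of 1.96 that stays the same with Chac1 at its bound (adjusted p = 1.22e-07, and 0.0368 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, was at least 34.2-fold higher, the cystine transporter gene Slc7a11 was 195-fold higher from 1 count (interval 34.6 to 7748), and the serine synthesis gene Psat1 rose by 4.43 (SE 0.17). Glycolysis genes rose in 13 cases and fell in 2 of 17 (13 and 2 adjusted over the list alone), with a median of 0.92 (adjusted p = 0.000203, and adjusted p = 0.103 with an estimated correlation). Hexokinase 2, encoded by Hk2, rose by 4.11 (SE 0.34), the phosphoglycerate mutase gene Pgam1 by 2.44 (SE 0.15), and the lactate dehydrogenase gene Ldha from 1104 ± 101 to 4487 ± 551 CPM. NRF2 targets held 8 higher and 1 lower of 12 (8 and 1 adjusted over the list alone), with a median of 1.79 (adjusted p = 0.000633, and adjusted p = 0.0720 with an estimated correlation). The oxidative stress genes Srxn1 and Nqo1 rose, Srxn1 by 6.87 (SE 0.42) and Nqo1 by 287-fold from 1 count (interval 51.1 to 11389).

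Naive and quiescence genes fell in 19 of 22 cases and rose in 3 (19 and 3 adjusted over the list alone), with a median log2 fold change of −3.00 (adjusted p = 9.81e-09, and 0.0348 with an estimated correlation). Dapl1, a marker of naive T cells, fell by 7.45 (SE 0.26), and Pik3ip1, encoding an inhibitor of PI3 kinase, fell by 5.19 (SE 0.28). Interferon-stimulated genes fell in 14 of 20 cases and rose in 0 (14 and 0 adjusted over the list alone), with a median of −1.37 (adjusted p = 0.000203, and adjusted p = 0.169 with an estimated correlation). Among them, the antiviral genes Ifit2 and Mx1 fell by 3.07 (SE 0.30) and 3.64 (SE 0.83). DYRK and CLK kinases and harmine targets held 1 higher and 7 lower of 11 (1 and 8 adjusted over the list alone), with a median of −0.60 (adjusted p = 0.0286, and adjusted p = 0.159 with an estimated correlation). Dyrk4, Maoa and Maob of this list did not enter the tests. The kinase genes Clk1 and Dyrk2 fell by 2.22 (SE 0.11) and 2.14 (SE 0.16). Dyrk1a itself was at 77.6 ± 5.58 CPM at 0 h and 52.0 ± 22.7 CPM at 5 h, a log2 fold change of −0.57 (SE 0.26, adjusted p = 0.0628, lower in 4 of 4 mice). It passed with mouse as a block (−0.64, adjusted p = 0.0297), with limma-voom (−0.70, adjusted p = 0.0308) and with DESeq2 size factors (−0.617, adjusted p = 0.0459). It also passed with upper-quartile factors (−0.685, adjusted p = 0.0265), with no filter on low counts (−0.569, adjusted p = 0.0130) and without the Th17 library of mouse 4 (−0.81, adjusted p = 0.0168). Without any 1 other library of this contrast it did not pass, at adjusted p from 0.0649 to 0.121. Without the Th17 library of mouse 2, at 20.5 CPM against 52.1 to 73.3 CPM in the other mice, the log2 fold change of Dyrk1a was −0.29 (adjusted p = 0.0847).

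NF-κB targets and immediate early genes went both ways. NF-κB targets held 13 higher and 3 lower of 18 (14 and 3 adjusted over the list alone), with a median log2 fold change of 1.08 (adjusted p = 0.00140, and adjusted p = 0.0720 with an estimated correlation). Tnfaip3, encoding the NF-κB inhibitor A20, fell from 2926 ± 203 to 103 ± 43.3 CPM, and the lymphotoxin β gene Ltb fell by 2.80 (SE 0.11). Immediate early genes held 11 higher and 7 lower of 21 (12 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.412). The AP-1 genes Jun and Fosb fell, Jun from 1114 ± 194 to 48.8 ± 10.4 CPM and Fosb by 5.44 (SE 0.41), while Fosl1 rose by 6.46 (SE 0.37) and the transcription factor gene Egr2 by 4.4 (SE 0.22). IL-6 and STAT3 targets held 8 higher and 2 lower of 14 (8 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.0607), but passed without the 5 h libraries of mouse 2 (adjusted p = 0.0193). Their cytokine signalling inhibitor Socs1 rose by 3.58 (SE 0.19).

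Genes of other T helper programs were also measured. The Treg program held 9 higher and 3 lower of 14 (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.68 (adjusted p = 0.0261, and adjusted p = 0.219 with an estimated correlation). Foxp3, the regulatory T cell transcription factor, was at 182 ± 39.0 CPM at 0 h and 215 ± 49.4 CPM at 5 h (log2 fold change 0.24, SE 0.17, adjusted p = 0.241, higher in 3 of 4 mice). It passed without the Th17 library of mouse 2 (0.38, adjusted p = 0.0291), and the log2 fold change of Foxp3 was 0.13 without the 0 h library of mouse 3 (adjusted p = 0.536) and 0.14 without the Th17 library of mouse 1 (adjusted p = 0.521). The Th1 program held 5 higher and 3 lower of 11 (5 and 3 adjusted over the list alone, adjusted p = 0.504), with Tbx21, the Th1 transcription factor, higher by 2.95 (SE 0.21) and the chemokine gene Ccl4 by 2.74 (SE 0.25). Ifng, encoding interferon γ, was at 11.3 ± 2.93 and 18.2 ± 8.51 CPM (0.68, SE 0.34, adjusted p = 0.0917, higher in 3 of 4 mice), and passed without the Th17 library of mouse 4 (0.87, adjusted p = 0.0322), while it was at 0.36 without that of mouse 2 (adjusted p = 0.343). The Th2 program held 2 higher and 3 lower of 8 (2 and 3 adjusted over the list alone, adjusted p = 0.792). Without the 5 h libraries of mouse 2, 4 of its genes were higher and 2 lower, and its median went from 0.135 to 0.674 (adjusted p = 0.521). Gata3, the Th2 transcription factor, fell by 2.34 (SE 0.18), while the chemokine receptor gene Ccr8 rose by 5.39 (SE 0.15) and Il4, encoding interleukin 4, by 3.64 (SE 0.49). TGF-β and SMAD targets held 5 higher and 5 lower of 13 (5 and 5 adjusted over the list alone, adjusted p = 0.998). Their median was −0.17 and their mean 0.04, and the test pointed up. The TGF-β feedback gene Pmepa1 rose by 4.81 (SE 0.13).

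The remaining pathway lists did not pass with stimulation. The counts higher and lower were 4 and 4 of 13 HIF targets (adjusted p = 0.792), 9 and 4 of 15 genes of the ER unfolded protein response (0.269), 7 and 6 of 24 G1-S and DNA replication genes (0.998), and 0 and 2 of 16 mitosis genes (0.269). For the 5 AHR targets measured of 12 listed they were 2 and 2 (0.803), and for 19 SR splicing factors 6 and 5 (0.668). Adjusted over the list alone, these counts held except for the SR splicing factors, with 7 and 5. For 16 p53 targets the counts were 6 and 6 (6 and 7 adjusted over the list alone, adjusted p = 0.913).

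**Figure D1:**
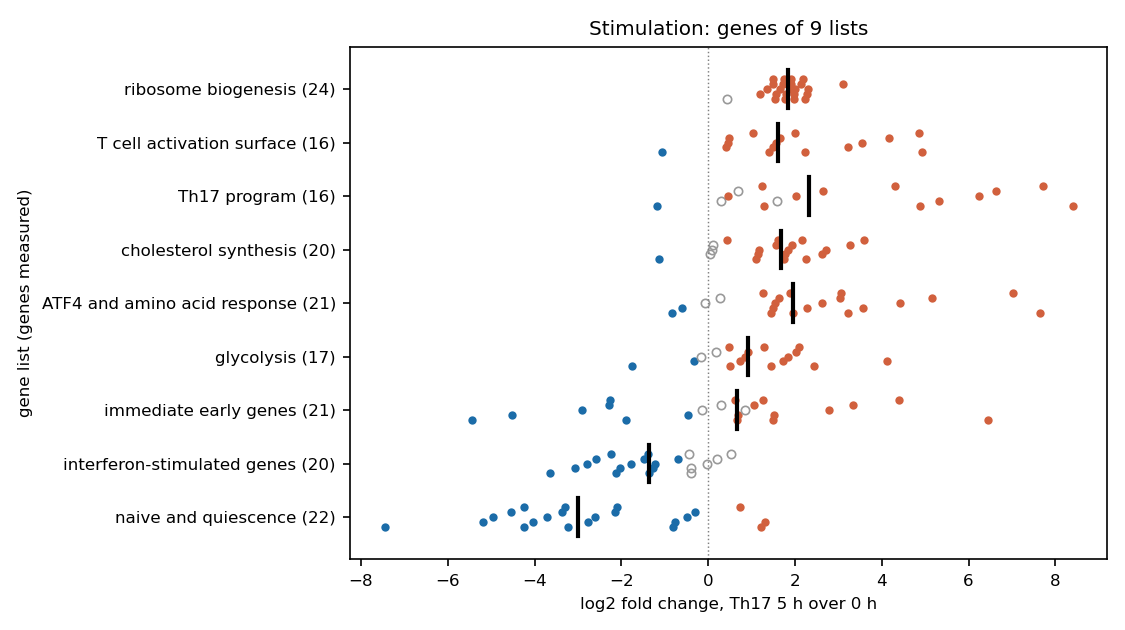
Log2 fold changes between 5 h in Th17 conditions and 0 h (horizontal axis) for the measured genes of 9 lists (vertical axis), with each point a gene and n = 4 mice per group. Red points passed the threshold and were higher, blue points passed and were lower, open points did not pass, and black bars are list medians, which run from −3.00 for naive and quiescence genes to 2.33 for the Th17 program.

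Markers of B cells, myeloid cells and NK cells fell over the 5 h. B cell markers took 0.149 ± 0.0139% of the counts at 0 h, 0.0340 ± 0.0108% in Th17 conditions and 0.0279 ± 0.0103% with harmine. Myeloid markers took 0.0620 ± 0.0192%, 0.0180 ± 0.00523% and 0.0131 ± 0.00338%, and NK cell markers 0.0272 ± 0.00320%, 0.0118 ± 0.00326% and 0.00831 ± 0.00101%. With stimulation, 8 of 10 B cell genes fell, with a median log2 fold change of −1.63 (adjusted p = 0.0286), as did 7 of 11 myeloid genes (−1.99, adjusted p = 0.0286) and 6 of 7 NK cell genes (−1.53, adjusted p = 0.0345). Adjusted over the list alone, 8, 7 and 7 fell, and with an estimated correlation the calls were lost, at adjusted p = 0.326, 0.353 and 0.326. Ighm, the immunoglobulin M heavy chain gene, fell from 1183 ± 92.8 to 258 ± 91.6 CPM, and the B cell receptor inhibitor gene Cd22 was 36.1-fold lower with 3 counts left at 5 h (interval 12.0 to 178). The macrophage genes Adgre1 and Csf1r fell by 6.26 (SE 0.67) and 4.27 (SE 0.48), and the NK cell genes Ncr1 and Gzma by 3.33 (SE 0.70) and 1.53 (SE 0.44). Of the CD4 T cell genes, 2 rose and 8 fell of 10 (2 and 8 adjusted over the list alone), with a median of −0.62 (adjusted p = 0.0345, and adjusted p = 0.326 with an estimated correlation), and Cd4 fell from 971 ± 24.9 to 166 ± 48.3 CPM.

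The other cell type lists did not pass with stimulation. None of 2 dendritic cell genes (adjusted p = 0.842) or 5 erythroid genes (adjusted p = 0.718) passed edgeR's test over all genes or adjusted over the list alone, and 0 did at an unadjusted p under 0.05, with DESeq2 or with limma-voom. With mouse as a block, edgeR called 2 erythroid genes lower, and without the 5 h libraries of mouse 2 it called 1 erythroid and 1 dendritic cell gene lower. Of 9 memory and effector genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.947), with a median of −0.02, a mean of 0.25 and a test that pointed down. Only 1 gene each was measured for CD8 T cells, where it fell but did not pass with mouse as a block, and for platelets, where by edgeR it passed adjusted over the list alone but not over all genes, while DESeq2, limma-voom and edgeR with mouse as a block called it over all genes.

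The second comparison asks what 10 µM harmine changed in Th17 conditions at 5 h. Of the list genes measured, 15 of 20 for cholesterol synthesis, 9 of 15 for the ER unfolded protein response and 10 of 17 for glycolysis fell with harmine, and 5 of 11 DYRK and CLK kinases and harmine targets rose. All 4 lists passed, but with an estimated correlation the calls of glycolysis (adjusted p = 0.176) and of the kinases (adjusted p = 0.0566) were lost. The mevalonate kinase gene Mvk fell from 18.6 ± 8.22 to 3.99 ± 1.54 CPM (mean ± SD, n = 4), a log2 fold change of −2.19 (SE 0.41). Aldoa, the aldolase A gene of glycolysis, fell from 1382 ± 186 to 808 ± 124 CPM (−0.77, SE 0.12), and Pdia4, encoding an ER protein folding enzyme, from 179 ± 10.8 to 82.1 ± 10.1 CPM (−1.13, SE 0.13). Clk1, a kinase of splicing factors, rose from 144 ± 15.4 to 271 ± 11 CPM (0.91, SE 0.11). Rorc was at 48.3 ± 11.4 CPM without and 49.2 ± 12.2 CPM with harmine and did not pass the test.

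By edgeR's quasi-likelihood test, 1977 of 10950 genes passed, 763 higher and 1214 lower with harmine. Of these, 240 were higher and 504 lower by at least 2-fold, and 3459 genes had an unadjusted p under 0.05. The count lower with harmine was 752 without the harmine library of mouse 1, the furthest move when 1 library was left out, and 717 when only the 8 libraries compared were fitted.

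The largest rise by the rule was that of Casc1, from 2.65 ± 1.46 to 19.1 ± 6.17 CPM (log2 fold change 2.85, SE 0.52, adjusted p = 0.00167). Nup210l, encoding a nucleoporin relative, rose by 2.84 (SE 0.59), and Dync2h1, encoding the heavy chain of cytoplasmic dynein 2, by 1.82 (SE 0.34). Gbp9, encoding an interferon-inducible GTPase, lies on chromosome 5 at 105077630 to 105139539 of GRCm38 (ENSMUSG00000029298). It rose from 34.95 ± 7.59 to 165 ± 27.2 CPM (2.24, SE 0.19, adjusted p = 5.72e-06), and its naive level was 117 ± 19.4 CPM. Rnf213, encoding a ubiquitin ligase, rose from 30.3 ± 7.69 to 112 ± 24.4 CPM (1.88, SE 0.21, adjusted p = 6.13e-05), and Phxr4 by 2.10 (SE 0.52). The largest fall was that of Crabp2, a retinoic acid binding protein gene, from 12.5 ± 4.78 to 1.46 ± 0.819 CPM (−3.05, SE 0.52, adjusted p = 0.00103). Pycr1, a proline synthesis gene on chromosome 11 at 120635712 to 120643769 (ENSMUSG00000025140), fell from 52.6 ± 19.4 to 7.82 ± 2.39 CPM (−2.73, SE 0.39, adjusted p = 0.000322). Ebpl and Crybg2 fell by 2.70 (SE 0.43) and 2.63 (SE 0.44), and Mboat1, encoding a lysophospholipid acyltransferase, fell by 2.56 (SE 0.36). The chemokine gene Ccl22 fell by 2.53 (SE 0.79, adjusted p = 0.0359). The call of Ccl22 was lost without the Th17 library of mouse 1 or 4 or the harmine library of mouse 1, 3 or 4, at adjusted p from 0.0670 to 0.135.

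Of the cholesterol synthesis genes, 15 of 20 fell and 0 rose (17 and 0 adjusted over the list alone), with a median log2 fold change of −0.70 (adjusted p = 5.76e-08, and 0.00927 with an estimated correlation). After Mvk, the largest falls were those of the sterol reductase genes Dhcr24 (−1.57, SE 0.30) and Dhcr7 (−1.52, SE 0.34) and the sterol dehydrogenase gene Nsdhl, from 46.9 ± 7.17 to 17.8 ± 4.10 CPM (−1.40, SE 0.20). Each fell in 4 of 4 mice. Genes of the ER unfolded protein response fell in 9 of 15 cases and rose in 1 (9 and 1 adjusted over the list alone), with a median of −0.48 (adjusted p = 0.000406, and 0.0403 with an estimated correlation). The ER chaperone genes Creld2 and Dnajc3 fell by 1.18 (SE 0.14) and 0.84 (SE 0.13). Xbp1, encoding the transcription factor of this response, fell from 341 ± 38.9 to 206 ± 6.94 CPM. Glycolysis genes fell in 10 of 17 cases and rose in 0 (11 and 0 adjusted over the list alone), with a median of −0.49 (adjusted p = 0.000228, and adjusted p = 0.176 with an estimated correlation). Its median was −0.33 without the 5 h libraries of mouse 2. The triose phosphate isomerase gene Tpi1 fell from 88.4 ± 6.75 to 40.0 ± 5.45 CPM (−1.14, SE 0.14), and the enolase gene Eno1 and the phosphofructokinase gene Pfkp fell by 0.88 (SE 0.11) and 0.79 (SE 0.14).

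DYRK and CLK kinases and harmine targets rose in 5 of 11 cases and fell in 0 (5 and 0 adjusted over the list alone), with a median log2 fold change of 0.61 (adjusted p = 0.000228, and adjusted p = 0.0566 with an estimated correlation). Of the 14 genes listed, Dyrk4 and the monoamine oxidase genes Maoa and Maob did not enter the tests, so the list says nothing about them. The median was 0.35 without the 5 h libraries of mouse 2, whose Th17 library lay lower than those of the other mice by a median of −0.60 over these genes. Besides Clk1, the splicing kinase genes Clk2 and Clk3 each rose by 0.67 (SE 0.14 and 0.12), and the kinase gene Dyrk1b by 1.34 (SE 0.38, adjusted p = 0.0222, higher in 4 of 4 mice). The call of Dyrk1b was lost without the harmine library of mouse 4 (1.06, adjusted p = 0.0883). The activity of the kinase DYRK1A was not measured. Its transcript, Dyrk1a on chromosome 16 at 94570010 to 94695517 (ENSMUSG00000022897), was at 52.0 ± 22.7 and 65.0 ± 6.38 CPM (0.32, SE 0.26, adjusted p = 0.429, higher in 3 of 4 mice), and the log2 fold change of Dyrk1a was 0.07 without the Th17 library of mouse 2 (adjusted p = 0.763), 0.09 without both 5 h libraries of mouse 2 (adjusted p = 0.713) and 0.57 without the Th17 library of mouse 4 (adjusted p = 0.161). IL-6 and STAT3 targets rose in 5 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.0139, and adjusted p = 0.176 with an estimated correlation). Il6st, the signalling chain of the interleukin 6 receptor, rose from 402 ± 171 to 791 ± 95 CPM (0.98, SE 0.25), the kinase gene Pim1 by 0.91 (SE 0.16) and the AP-1 gene Fosl2 by 0.84 (SE 0.16). The cytokine receptor kinase gene Jak3 fell by 1.09 (SE 0.25). The Th17 library of mouse 2 had 151 CPM of Il6st, against 439 to 522 CPM in the other mice.

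**Figure D2:**
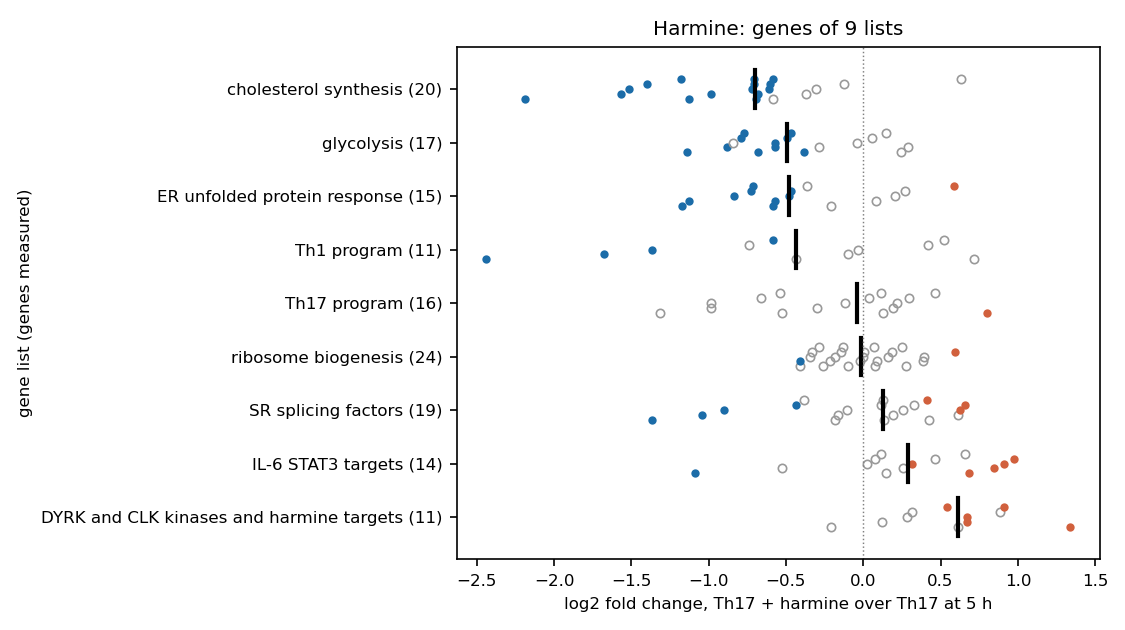
Log2 fold changes between Th17 conditions with and without harmine at 5 h (horizontal axis) for the measured genes of 9 lists (vertical axis), with each point a gene and n = 4 mice per group. Red points passed the threshold and were higher, blue points passed and were lower, open points did not pass, and black bars are list medians, which run from −0.70 for cholesterol synthesis to 0.61 for DYRK and CLK kinases and harmine targets.

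The Th17 program did not pass with harmine. Of its 16 measured genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), and the median log2 fold change was −0.04 (adjusted p = 0.938), with a mean of −0.20 and a test that pointed up. The gene that rose was Nfkbiz, encoding the nuclear NF-κB regulator IκBζ, from 105 ± 20.3 to 183 ± 13.0 CPM (0.80, SE 0.15, adjusted p = 0.00188, higher in 4 of 4 mice). Il17f, on chromosome 1 at 20777146 to 20790617 (ENSMUSG00000041872), was at 42.7 ± 27.2 CPM without and 21.5 ± 9.18 CPM with harmine (−0.98, SE 0.42, adjusted p = 0.116, lower in 4 of 4 mice). With mouse as a block it passed (−0.88, adjusted p = 0.0441), as it did with no filter on low counts (−0.94, adjusted p = 0.0118). The Th17 library of mouse 2 had 81.3 CPM against 22.0 to 42.5 CPM in the other mice, and the log2 fold change of Il17f was −0.44 without it (adjusted p = 0.431), −1.29 without the harmine library of that mouse (adjusted p = 0.0597) and −0.79 without both (adjusted p = 0.124). Il17a, at 20730905 to 20734496 of the same chromosome (ENSMUSG00000025929), was at 7.46 ± 5.39 and 3.73 ± 3.49 CPM (−0.98, SE 0.69, adjusted p = 0.352, lower in 4 of 4 mice). Without the same libraries of mouse 2, the log2 fold change of Il17a was −0.38, −1.70 and −1.14 (adjusted p = 0.762, 0.135 and 0.284), and without the harmine library of mouse 1 it was −0.56 (adjusted p = 0.635). Rorc, on chromosome 3 at 94372794 to 94398276 (ENSMUSG00000028150), had a log2 fold change of 0.03 (SE 0.25, adjusted p = 0.943, higher in 2 of 4 mice). On simulated counts, 70% of genes changed by 2-fold and 24% of those changed by 1.5-fold were recovered. All the changed genes had a mean of at least 10 CPM in Th17 conditions, so these shares do not cover Il17a. Only 200 genes were changed there, while 1977 passed in the data, so the shares may differ for the real test.

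**Figure D3:**
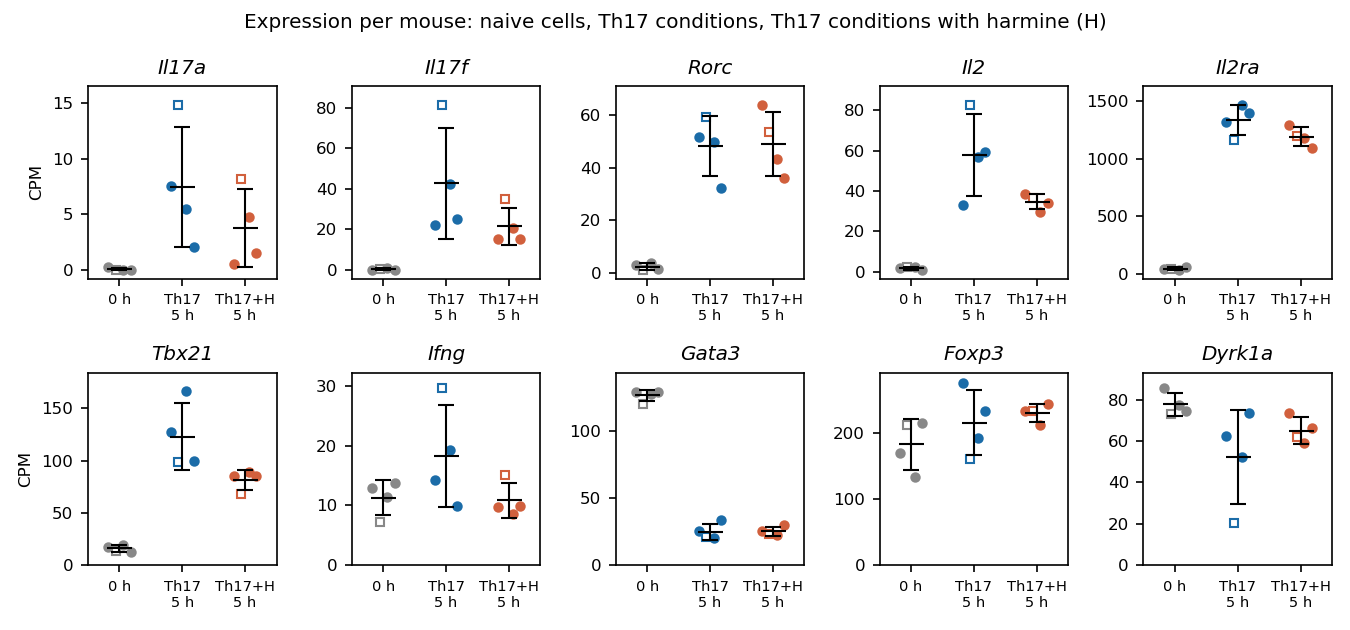
Expression in CPM (vertical axes, linear) of 10 genes fixed beforehand, in naive cells at 0 h, Th17 conditions at 5 h and Th17 conditions with harmine (H) at 5 h. Each point is 1 library, open squares are mouse 2, and lines and bars are the mean ± SD of 4 mice, as in Il17f, which goes from 0.418 at 0 h to 42.7 without and 21.5 with harmine.

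Genes of other T helper programs differed in part. The Th1 program held 4 lower and 0 higher of 11 (4 and 0 adjusted over the list alone), with a median log2 fold change of −0.44, and the list did not pass (adjusted p = 0.114). Gzmb, encoding the cytotoxic protease granzyme B, fell from 45.2 ± 18.2 to 8.32 ± 2.18 CPM (−2.44, SE 0.29, adjusted p = 7.82e-05), and the chemokine genes Ccl3 and Ccl4 fell by 1.68 (SE 0.32) and 1.36 (SE 0.23). Tbx21 fell from 123 ± 32.0 to 81.8 ± 9.54 CPM (−0.59, SE 0.19, adjusted p = 0.0377), and each of these 4 genes was lower in 4 of 4 mice. The call of Tbx21 was lost without the Th17 library of mouse 1 or 3 or without any 1 of the harmine libraries, at adjusted p from 0.0593 to 0.184, and the log2 fold change of Tbx21 was −0.36 without the Th17 library of mouse 3. Ifng was at 18.2 ± 8.51 and 10.8 ± 2.91 CPM (−0.74, SE 0.34, adjusted p = 0.142, lower in 3 of 4 mice), and the log2 fold change of Ifng was −0.38 without the Th17 library of mouse 2 (adjusted p = 0.441) and −0.59 without both 5 h libraries of mouse 2 (adjusted p = 0.210). The Th2 program held 2 lower and 0 higher of 8 (2 and 0 adjusted over the list alone, adjusted p = 0.649). Ccr8 fell from 661 ± 86.6 to 357 ± 30.5 CPM (−0.89, SE 0.12), and Il4 fell by 1.30 (SE 0.41, adjusted p = 0.0376, lower in 4 of 4 mice). The call of Il4 was lost with mouse as a block (adjusted p = 0.0647). It was also lost without the Th17 library of mouse 1, 2 or 4 or any harmine library, at 0.0521 to 0.116, and without both 5 h libraries of mouse 2 (adjusted p = 0.144). Gata3 was at 24.8 ± 6.08 and 25.03 ± 3.15 CPM (0.01, SE 0.18, adjusted p = 0.981, higher in 2 of 4 mice). The Treg program held 3 lower and 0 higher of 14 (3 and 0 adjusted over the list alone, adjusted p = 0.938), and Foxp3 was at 215 ± 49.4 and 230 ± 13.5 CPM (0.10, SE 0.17, adjusted p = 0.742, higher in 3 of 4 mice). The log2 fold change of Foxp3 was 0.23, 0.00 and 0.18 without the Th17 libraries of mice 1, 2 and 4 (adjusted p = 0.404, 0.998 and 0.574), and −0.01 without both 5 h libraries of mouse 2.

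Il2 was at 57.8 ± 20.3 CPM without and 34.6 ± 3.73 CPM with harmine (−0.74, SE 0.25, adjusted p = 0.0460, lower in 3 of 4 mice). This call was lost with mouse as a block (adjusted p = 0.0687) and without any 1 of the 8 libraries except the Th17 library of mouse 1, at adjusted p from 0.0802 to 0.126. Other settings that lost it were DESeq2 size factors (adjusted p = 0.0556), limma-voom (0.0546) and the stricter filter (0.0544). So did the fit of only the 8 libraries compared (0.0777) and that without both 5 h libraries of mouse 2 (0.118). Il2ra was at 1335 ± 129 and 1191 ± 82.2 CPM (−0.16, SE 0.14, adjusted p = 0.466, lower in 3 of 4 mice), and the log2 fold change of Il2ra was −0.08 and −0.10 without the Th17 libraries of mice 3 and 4 (adjusted p = 0.786 and 0.714). IL-2 and STAT5 targets held 1 lower and 0 higher of 12 (0 and 0 adjusted over the list alone, adjusted p = 0.940). T cell activation surface genes held 3 higher and 4 lower of 16 (4 and 4 adjusted over the list alone, adjusted p = 0.864), with a median of 0.03 and a mean of −0.12. Tnfrsf9 fell from 1029 ± 122 to 419 ± 27.9 CPM (−1.30, SE 0.14, adjusted p = 4.07e-05) and Tnfrsf4 by 0.83 (SE 0.15). NF-κB targets held 2 higher and 4 lower of 18 (2 and 6 adjusted over the list alone, adjusted p = 0.207). Immediate early genes held 4 higher and 2 lower of 21 (4 and 2 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0745), and the list passed without the 5 h libraries of mouse 2 (adjusted p = 0.0397). The immediate early list also passed with a trend of gene length and GC content removed (adjusted p = 0.00148), where the median of its log2 CPM differences went from 0.19 to 0.33. The orphan nuclear receptor gene Nr4a2 rose from 208 ± 8.37 to 363 ± 19.1 CPM (0.80, SE 0.11), and the stress response gene Ier3 fell by 1.44 (SE 0.34).

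SR splicing factors went both ways, with 3 higher and 4 lower of 19 (5 and 4 adjusted over the list alone, adjusted p = 0.813), a median of 0.13 and a mean of −0.04. Srsf3, Srsf7 and Srsf2 fell by 1.37 (SE 0.14), 1.04 (SE 0.16) and 0.90 (SE 0.16), and the splicing coactivator gene Srrm2 rose from 499 ± 39.7 to 785 ± 42.2 CPM (0.65, SE 0.10). The Th17 library of mouse 2 had 668 CPM of Srsf3, against 416 to 448 CPM in the other mice. Naive and quiescence genes held 3 higher and 2 lower of 22 (5 and 2 adjusted over the list alone, adjusted p = 0.193). S1pr1, the receptor for exit from lymphoid organs, rose by 0.81 (SE 0.12), and the growth factor binding protein gene Igfbp4 fell by 1.25 (SE 0.16). Interferon-stimulated genes held 3 higher and 3 lower of 20 (6 and 4 adjusted over the list alone, adjusted p = 0.403). Without the 5 h libraries of mouse 2, 6 of them were higher and 2 lower, and their median went from 0.092 to 0.27. The counts were then 6 and 2 for naive and quiescence genes and 6 and 4 for SR splicing factors, and none of these lists passed. The antiviral gene Oasl2 rose from 3.36 ± 1.90 to 12.1 ± 5.43 CPM (1.86, SE 0.42, adjusted p = 0.00660, higher in 3 of 4 mice), and the nucleic acid sensor gene Zbp1 by 0.84 (SE 0.18). The ATF4 and amino acid response held 2 higher and 5 lower of 21 (2 and 6 adjusted over the list alone, adjusted p = 0.257). Phgdh, the first enzyme of serine synthesis, fell from 905 ± 114 to 371 ± 83.5 CPM (−1.29, SE 0.14, adjusted p = 5.21e-05), while Chac1 rose from 6.70 ± 4.15 to 22.1 ± 5.96 CPM (1.71, SE 0.42, adjusted p = 0.0130).

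The remaining lists did not pass with harmine. Ribosome biogenesis genes held 1 higher and 1 lower of 24 (1 and 0 adjusted over the list alone, adjusted p = 0.938), with a median log2 fold change of −0.01 and a test that pointed up. The counts higher and lower were 2 and 1 of 13 TGF-β and SMAD targets (adjusted p = 0.207), 0 and 2 of 24 G1-S and DNA replication genes (0.749), 1 and 0 of 5 AHR targets (0.807), and 1 and 4 of 12 NRF2 targets (0.611), and these held adjusted over the list alone. Of 12 AHR targets listed, only these 5 were measured, which limits what the list can show. With mouse as a block, the counts were 0 and 1 for TGF-β and SMAD targets and 1 and 1 for AHR targets. Without the block, the counts were 1 and 2 of 15 NFAT targets (1 and 3 adjusted over the list alone, adjusted p = 0.813), whose median was 0.06 and mean −0.08, and 0 and 1 of 13 HIF targets (0 and 0 adjusted over the list alone, adjusted p = 0.286). No mitosis gene of 16 (adjusted p = 0.864) and no p53 target of 16 (adjusted p = 0.938) passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 mitosis genes and 3 p53 targets, while DESeq2 called 0 and 2 and limma-voom 0 and 1. With mouse as a block edgeR called 0 and 1, and without the 5 h libraries of mouse 2 it called 0 and 2.

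Cell type lists did not pass with harmine either. CD4 T cell genes held 0 higher and 3 lower of 10 (1 and 4 adjusted over the list alone, adjusted p = 0.449), and Cd4 fell from 166 ± 48.3 to 87.9 ± 12.4 CPM (−0.92, SE 0.18, adjusted p = 0.00277, lower in 4 of 4 mice). Myeloid genes held 1 lower of 11 (2 lower adjusted over the list alone, adjusted p = 0.415). The gene was the macrophage marker Cd68, at 8.59 ± 3.18 and 3.56 ± 0.642 CPM (−1.25, SE 0.38, adjusted p = 0.0298, lower in 4 of 4 mice). Its call was lost without the Th17 library of mouse 2 or 4 or any harmine library, at adjusted p from 0.0514 to 0.0825. It was lost too with limma-voom (adjusted p = 0.177), with only the 8 libraries compared (0.0513) and without both 5 h libraries of mouse 2 (0.0884). No B cell gene of 10 (adjusted p = 0.872), NK cell gene of 7 (0.449) or erythroid gene of 5 (0.924) passed edgeR's test over all genes or adjusted over the list alone, and DESeq2 and limma-voom called 0 in each. At an unadjusted p under 0.05 there were 0, 1 and 0, and Ighm was at 258 ± 91.6 and 202 ± 104 CPM. The counts lower were 1 of 2 dendritic cell genes (adjusted p = 0.449) and 1 of 9 memory and effector genes (adjusted p = 0.872), with 0 higher, and both held adjusted over the list alone. The single CD8 T cell gene measured was lower (−0.92), a call lost without the 5 h libraries of mouse 2 (−0.61), and the single platelet gene did not pass. The median and mean of the erythroid list were −0.24 and −0.25, while its test pointed up.

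The last comparison asks how the harmine change sits on the stimulation change. Of the 1895 genes that stimulation raised by at least 2-fold, 246 (13.0%) were lower with harmine, Pycr1, Phgdh and Tnfrsf9 among them, and 68 were higher. Independent lists of these sizes would share 210 and 132 genes. Of the 2272 genes that stimulation lowered by at least 2-fold, 218 were higher with harmine, Gbp9 and Clk1 among them, and 243 were lower, against 158 and 252 for independent lists. The size of the harmine change was also set against the stimulation change of the same gene. The median ratio of harmine to stimulation change was −34.6% over the 16 cholesterol genes that rose, −48% over 9 genes of the ER unfolded protein response, −27.3% over 13 glycolysis genes, −1.30% over 23 ribosome biogenesis genes and 0.5% over 15 activation surface genes. With separate Th17 libraries for the 2 contrasts, which was tried after these ratios were seen, no harmine change would give 0. The medians then ran over 6 splits from −34.8 to −26.5% for cholesterol, −78.7 to −26.9% for ER, −35.3 to −19.8% for glycolysis, −12.6 to −0.400% for ribosome biogenesis and −4.80 to 3.50% for activation surface genes.

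The Th17 libraries without harmine enter both contrasts with opposite sign. Simulated groups with no effect gave a correlation of −0.508 across genes, and the observed correlation was −0.115. The covariance was −0.125 observed and −0.0710 simulated, a difference of −0.0540. The simulation drew each library independently and left out the pairing by mouse, so the value expected with no effect is uncertain. With the Th17 libraries split into 2 for each contrast, the mean over 6 splits was 160 raised genes lower with harmine, against 148 for independent lists, and the covariance ran from −0.129 to −0.0220. The count lay above that of independent lists in the 3 splits with the Th17 library of mouse 2 in the harmine contrast (207 against 190, 207 against 176 and 238 against 209). It lay below in the other 3 splits (115 against 119, 102 against 103 and 91 against 93.5). Raised genes higher with harmine had a mean of 55 against 83.7, below independent lists in 6 of 6 splits. Of the lowered genes, a mean of 115 were then higher with harmine, against 98.2 for independent lists, and 199.7 were lower, against 174, above independent lists in 6 and 5 of the 6 splits. The count of 246 was 134 without the harmine library of mouse 1.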

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

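The tests of labels swapped within mouse 2, of gene length and GC content, and of the position along the stimulation response were written before their results were seen, and the length and GC test was divided by library afterwards. The values of each library were compared with the other 3 of its group by the gap to the nearest library over the range of the group, and a ratio above 0.829 is listed here. Chance gives about 1 in 20 groups. Among the groups of the genes in the text, 33 of 330 were listed, where chance would give 16.5, and 16 of the 33 concerned mouse 2, 13 of them in Th17 conditions. Groups with 3 libraries at 0 counts were left out, a choice made after the list was seen.

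In the Th17 library of mouse 2, the mitochondrial share (ratio 0.863) and the ribosomal protein share (0.874) lay above the other mice, 2 of 24 groups of library measures. Cd4 was at 94.3 CPM there against 185 to 196 CPM (ratio 0.920), Il6st at 151 against 439 to 522 (0.859), Jak3 at 79.8 against 201 to 242 (0.831), and Tnfaip3 at 40.2 against 115 to 139 (0.849). Sema7a (0.869) and Sqle (0.898) were also lower than in the other mice. Srsf7 was at 1057 CPM against 577 to 607 (0.918), Srsf3 at 668 against 416 to 448 (0.843), Nhp2 at 655 against 372 to 378 (0.972) and Tnfrsf4 at 1573 against 1132 to 1195 (0.835). Gar1 (0.910), Socs1 (0.941) and Bst2 (0.917) were higher too. In the harmine library of mouse 2, Jak3 (0.846) and Egr2 (0.874) were lower.

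The remaining values were spread over the mice and groups. In Th17 conditions, Casc1 stood apart in mouse 1 (0.851) and Fosb in mouse 3 (0.950). With harmine, Ccl3 (0.884) and Tnfaip3 (0.890) stood apart in mouse 1, and Dkc1 (0.937) and Pmepa1 (0.926) in mouse 3. At 0 h, Ccl4 (0.879) and Tet1 (0.863) stood apart in mouse 1, Gata3 (0.871) in mouse 2, and Dhcr24 (0.873), Ncr1 (0.940) and Pdcd1 (0.838) in mouse 4. In mouse 3 at 0 h, the myeloid genes Adgre1 (0.879, 16.8 CPM against 38.8 to 43.4) and Cd68 (0.875, 16.1 against 39.9 to 45.4) were lower, as were Dhcr7 (0.860) and Eno1 (0.920), and Clk1 (0.907) and Gzmb (0.938) were higher.

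The 5 h libraries of mouse 2 deviated from the other mice with an SD over genes of 0.817 in Th17 conditions and 0.702 with harmine, against at most 0.545 and 0.509 for another mouse. A swap of the 2 labels is argued against, since on the genes that harmine changed in the other mice, where the Th17 mean is 0 and the harmine mean 1, the Th17 library lay at −0.00800 and the harmine library at 0.914. A position further along the stimulation response is argued against too, since the deviations correlated with the stimulation change across genes at only 0.0140 and 0.0640. Length and GC content gave an R squared of 0.0180 with the deviation in the harmine library, which argues against them there, but 0.265 in the Th17 library, between the bounds set for and against, so there they may account for part of it and cannot be told apart from other causes. No other biological explanation was tested, and a test of library depth was dropped after its values were seen, 3655843 and 3896606 counts within a range of 3405537 to 4355566 for the other mice.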

How the results depend on the processing

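The fit without the 5 h libraries of mouse 2 was chosen only after the data were seen, and the other alternatives were planned. The 7 counts of genes kept within 1.5 times of their values under DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, limma-voom, both filters, the fit with mouse as a block and the fit without mouse 2. With harmine, the block gave 1793 genes, DESeq2 2288 and limma-voom 1947, and 1713 of the 1977 genes were shared with the block. Fitting only the 8 libraries compared gave 1271 genes with harmine, 717 of them lower, and the cause was not tested. A bound of 2-fold by construction left 744 genes with harmine (240 higher, 504 lower), 4167 with stimulation (1895 higher), and 83 genes raised by stimulation and lower with harmine instead of 246. With the Th17 libraries split the 246 became 160, with fewer libraries per contrast and none shared, and the cause was not tested further. Leaving out 1 library gave 752 to 1315 genes lower with harmine and 134 to 254 raised genes lower with harmine, both lowest without the harmine library of mouse 1. Upper-quartile factors shifted the median stimulation change of all genes from −0.02 to −0.13.

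Of 89 harmine genes past the threshold that the rule names, 23 lost their call without some single library, 5 with mouse as a block and 9 without mouse 2. Of 124 stimulation genes, 6, 2 and 1 did. The block changed no list call. Directions turned only for values that did not pass, and the cause was not tested. Without mouse 2, the harmine log2 fold changes became 0.18 for Hbb-bs, 0.024 for Hba-a1, −0.011 for Foxp3 and −0.023 for Gata3. The test of these lists then pointed the other way, with medians of 0.013 for IL-2 and STAT5 targets and −0.007 for mitosis genes with harmine, and −0.24 for TGF-β targets, 0.03 for G1-S genes and 0.52 for dendritic cell genes with stimulation. With the block it turned for erythroid genes with harmine (median −0.14) and for TGF-β (−0.17) and G1-S genes (−0.12) with stimulation. With fry, which does not compare with other genes, it turned for the Th17 program (−0.043), p53 targets (0.11), SR splicing factors (0.13) and erythroid genes (−0.24) with harmine and for memory genes (−0.024) with stimulation. In addition, 15 list results that had not passed camera passed fry. With harmine these included the Th1 program (adjusted p by fry = 0.000999), immediate early genes (0.00445) and TGF-β targets (0.0104). NF-κB targets (0.0137), the Th2 program (0.0237) and HIF targets (0.0348) passed fry too. Leaving out 1 library gave harmine changes of −0.10 to 0.49 for Top2a, −0.59 to 0.51 for Hbb-bs, −0.52 to 0.31 for Hba-a1, −0.078 to 0.173 for Rorc and −0.078 to 0.229 for Gata3, and stimulation changes of −0.35 to 0.10 for Bst2 and −0.97 to 0.10 for Hbb-bs. At this depth, and with 4 libraries per group, 24% of genes changed by 1.5-fold were recovered in the simulated harmine contrast. These genes all had a mean of at least 10 CPM in Th17 conditions, and depth was not separated from the spread between mice. The simulation changed 200 genes, while 1977 passed with harmine in the data. The adjusted p depends on that number, so the share recovered may differ in the data.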

Other observations

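The tests of genomic DNA by density, of a uniformly weaker stimulation and of mouse 2 in the list results were chosen only after their results were seen, as were the gene classes in the next paragraph. The tests of low counts, introns, length and GC content, and other splits of the libraries were written before, while mouse as a block in the length and GC test and the restriction to splits that part all pairs came after. The density test replaced a ratio test written before, once that had decided nothing, and a test of mouse 2 for the non-coding genes was dropped after its value was seen.

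Non-coding genes, a class of 544 tested genes with antisense, intergenic, intronic and uncharacterised transcripts, were higher with harmine, with a median log2 fold change of 0.57 against −0.08 over protein-coding genes. By edgeR's test 89 rose and 12 fell, and the class passed camera at p = 6.41e-10, or p = 0.0180 with an estimated correlation. The median was 0.646 without the 5 h libraries of mouse 2. Non-coding genes as a whole, tested or not, took 0.938 ± 0.0477% of the counts in Th17 conditions, 1.16 ± 0.0315% with harmine and 1.26 ± 0.0907% at 0 h (n = 4). Of 156 lincRNAs, 11 rose and 6 fell (median 0.21), of 130 transcripts in the class to be experimentally tested 39 and 1 (1.16), of 115 antisense genes 15 and 1 (0.57), and of 100 processed transcripts 17 and 4 (0.28). Of 25 T cell receptor joining segments, which lie between the variable and constant segments, 7 rose and 0 fell, with a median of 0.88. Of 75 variable segments, 0 passed edgeR's test over all genes, with or without mouse as a block, DESeq2 or limma-voom, 3 had an unadjusted p under 0.05, and their median was −0.05. Neither set of segments was tested as a list, nor was the difference between them.

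For the non-coding genes, genomic DNA is argued against, since isolated untested genes gained at most −8e-04 CPM per kb in any mouse with harmine, while the non-coding genes gained 0.711 to 1.27. The earlier ratio test decided nothing, since the harmine to Th17 ratio of isolated genes with almost no counts lay below that of the non-coding genes in 3 of 4 mice. A bias of low counts is argued against, since the class median lay at percentile 100 of 10000 lists of protein-coding genes matched on expression, whose highest median was −0.06. Intron RNA of surrounding genes is a candidate explanation, though reads over introns, which would test for unspliced RNA, were not counted here. The 317 genes that overlap a tested protein-coding gene, by any length and on either strand, had a median higher by 0.472 than the 227 outside (0.78 against 0.31, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The permutation treats genes as independent. Overlap with introns was not separated from overlap with exons, so this difference cannot tell intron RNA from reads of shared exons.

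For the cholesterol, ER and glycolysis lists, a uniformly weaker stimulation would give 1 ratio of harmine to stimulation change for every list that rose. The median ratio differed by 0.333 between ribosome biogenesis and cholesterol genes (permutation p = 1e-05, the smallest that 100000 permutations can give). It differed by 0.139 to 0.344 in 6 fits with separate Th17 libraries for the 2 contrasts, all with the same harmine libraries. These 2 lists were chosen after their results were seen, which the permutation ignores, so its p cannot decide against a weaker stimulation. The values show only that the ratio was not the same in these 2 lists. The permutation treats genes as independent and does not measure the spread between mice. A trend with length and GC content is argued against as the whole cause, since with the trend removed the largest adjusted p of the 3 lists was 0.00148, or 0.00173 with mouse as a block, with medians of −0.64, −0.37 and −0.33, although the harmine change did follow length across genes (rho 0.222, genes not being independent). The mouse 2 libraries are argued against, since the largest adjusted p of the 3 lists without them was 8.1e-05. An effect of harmine on these lists stays open and was not tested further, and the test of glycolysis was lost with an estimated correlation (adjusted p = 0.176).

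The counts of genes were also set against other splits of the libraries. The same mice gave a library to each group, so the real split compares with the splits that part all 4 pairs of libraries from the same mouse, and these 8 splits are too few for a share under 0.05. That share had been set over all 35 splits of 8 libraries into 4 and 4, which leaves the pairing out. At 5 h, 1 of the 35 splits gave as many genes as the real 1977, the real split itself, and the highest of the other splits was 0 by edgeR. At an unadjusted p under 0.05, the other splits gave 171 to 1531 genes and the real split 3459. Of the 35 splits for stimulation, 1 gave as many as the real 6568, again the real one, and the highest other was 0 by edgeR, with 38 to 1431 genes at an unadjusted p under 0.05 against 6982. The splits that part all 4 pairs and those that part fewer gave 0 genes alike, apart from the real split. No other tool was run on the splits.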
